A study of Mus musculus with 8 samples.

How the data were processed

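ChIP-seq was measured in O4-positive cells, sorted magnetically from wild-type mice at postnatal day 7; the labels give cortex and corpus callosum as the tissue and OPC as the cell. Antibodies were anti-Chd7 (Cell Signaling), anti-Chd8 (Bethyl) and rabbit IgG for the mocks, by the labels of each sample, which were used. The extraction notes instead name the O4 antibody for isolating the remodeler complexes, and this difference is unresolved. Libraries were grouped by their titles into Chd7 ChIP (replicates 1 and 2), Chd8 ChIP (1 library), mock (1 library for Chd7 replicate 1, and 1 that the labels assign to both Chd7 replicate 2 and Chd8) and input (3 libraries, 1 for each ChIP). Whether the replicates came from separate animals or litters is not given in the sources used here. The track names inside the Chd7 replicate 2 and Chd8 files carry other replicate numbers than the titles, 3 for Chd7 and 2 for Chd8. The titles and the control assignments in the labels were used, and every setting with matching inputs rests on them; by the track numbers, inputs 2 and 3 would change places.

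The deposited files are broad peak lists of mm10, 1 per library, and the submitters' processing notes name Bowtie2, SAMtools, Picard and MACS, whose versions, settings and calling controls are not given in the sources used here. Column 5 holds a score per peak that the authors' caller gave, 10 times the −log10 q to within 1 unit. Column 7 holds the fold of each peak over the caller's local background, a ratio computed by the authors. Columns 8 and 9 hold the −log10 p and −log10 q of each peak, computed by the authors. The lowest −log10 q in any list was 1.30. Peak numbers in the names run higher than the listed peaks, up to 69048 for Chd7 replicate 2 and 264855 for input 3, so the authors had dropped peaks by steps not given in the sources used here. Fold depends on the caller, its control and the depth of each library, so levels of fold were not compared between libraries. Means of both Chd7 folds and geometric means of Chd7 and Chd8 fold served to rank and describe sites, although the libraries differ in scale. Reads were not used here, and depth is unknown. The precision of shares was therefore set by the number of peaks or genes.

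Peaks that touched a peak of either mock by at least 1 bp were removed from the ChIP lists. Reproducible Chd7 regions were the merged spans of replicate 1 and replicate 2 peaks that overlapped by at least 1 bp, and their fold was the mean over both libraries of the highest peak in each. Overlaps of lists were tested against 1000 random placements, each peak moved within its own chromosome with its length kept (one-sided permutation p). Median folds were compared by 100000 two-sided permutations over peaks. Location was read from peak midpoints beside the mean of 100 random placements. Intervals of shares are 95% Clopper-Pearson intervals, and intervals of odds ratios are Woolf intervals.

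Genes came from a RefSeq table of the same build with 21887 protein-coding genes, which gives boundaries but no strand or exons. Promoters planned as start sites within 1 kb therefore became gene ends, either boundary of a protein-coding gene within 1 kb. A locus was the gene body with 10 kb on both sides, where 10 kb upstream had been planned, and exons and introns were joined into 1 class. Of the genes longer than the window with a peak at an end, 0.193% for Chd7 and 3.99% for Chd8 had peaks at both ends. The planned motif densities and lists matched on CpG content need the genome sequence and were not run. Co-occupancy and lists at gene ends were tested by two-sided Fisher's exact tests over protein-coding genes. Loci were tested by a two-sided permutation p over 10000 random lists matched on locus length decile (smallest p 2e-04). The direct comparison of Chd7 with Chd8 used Fisher's exact test among genes with either at the locus, without length matching. Each family of 15 lists was adjusted by Benjamini-Hochberg, with a threshold of 0.05. The lists held 578 entries, 558 distinct genes, all of which matched the table by symbol. Such p-values compare gene lists within these libraries, not animals.

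The lists, the tests, the naming rule and most alternatives were chosen before the data were examined. Named were, for each of the Chd7, Chd8 and shared sets, the 10 genes with the highest fold at a gene end, the 10 OPC identity or oligodendrocyte differentiation members with the highest fold at the locus, the 2 top members of every other list, and always Olig1, Olig2, Sox10, Pdgfra, Myrf, Mbp, Nkx2-2, Trp53, Cdkn1a, Chd7 and Chd8. Some genes that this rule names are not reported here. Alternatives were peaks with a −log10 q of at least 5 or a fold of at least 5, equal numbers of highest-fold peaks, mock-touching peaks kept, peaks of the matching input removed, sex chromosomes left out, a reciprocal overlap of 50%, each Chd7 library alone, placements drawn from input regions, gene-end windows of 5 kb and a background of genes with an end in 2 or more inputs. Added after the data were seen were placements matched on gene ends, removal of peaks within 10 kb of a mock peak, the nearest gene end alone, removal of peaks under any input and regions away from gene ends. In judging direction, a list without a bound member where fewer than 1 was expected was given none, a rule set after the first output.

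Methods were tested on simulated data. Of 200 unrelated lists, 13 gave an overlap p under 0.05, and a planted overlap of 5% was recovered as 5.16%. These lists were placed by the same random draw as the test, with fewer placements per test than in the results. Clustering of real peaks at gene ends was therefore not tried. Among 1500 simulated lists without enrichment, 5 were called at the Chd7 rate and 1 at the Chd8 rate. Lists raised from 5% to 25% or from 41% to 75% were called in 90 and 98 of 100 rounds. Where occupancy rose with length alone, 1 of 600 lists was called with matched lengths at each rate, and 1 and 109 without matching. Of 200 equal sets of simulated values, 9 gave a median-fold p under 0.05, with fewer permutations than in the results. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.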

Results

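Chromatin occupancy of Chd7 and Chd8, ATP-dependent chromatin remodelers of the CHD family, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in O4-positive cells of wild-type mice at postnatal day 7. O4 is a surface antigen of the oligodendrocyte lineage, and the labels call the sorted cells oligodendrocyte precursor cells (OPCs). The 8 libraries comprised 2 Chd7 ChIPs, 1 Chd8 ChIP, 2 mock ChIPs with rabbit IgG and 3 inputs. Chd7 replicate 2 and the Chd8 library shared a mock, whereas Chd7 replicate 1 had its own. Chd8 had no replicate, so no replicate error could be given for any Chd8 value. The peak lists hold no read counts, so the depth of each library is unknown, and the intervals given are 95% exact binomial (Clopper-Pearson) intervals over peaks or genes, which cover counting error only.

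The lists held 5282 peaks for Chd7 replicate 1, 6292 for Chd7 replicate 2 and 18415 for Chd8. The mocks held 89 and 98 peaks, and the inputs held 109486, 178478 and 91628. Chd7 peaks covered 1.61 Mb and 2.30 Mb of the mouse genome (mm10), Chd8 peaks 8.83 Mb, and input peaks 40.7 Mb, 81.5 Mb and 34.2 Mb. Median fold over the caller's background was 4.60 and 3.34 for Chd7 replicates 1 and 2, 4.47 for Chd8, and 3.79, 3.62 and 3.50 for the inputs. Mock peaks touched 1.21% of Chd7 replicate 1 peaks, 0.874% of replicate 2 peaks and 0.353% of Chd8 peaks, and these were removed, which left 5218, 6237 and 18350 peaks. Peaks of the matching input overlapped 16.0% (15.04 to 17.0) of the Chd7 replicate 1 list, 33.4% (32.2 to 34.6) of the replicate 2 list and 40.5% (39.8 to 41.2) of the Chd8 list, and these peaks were kept. Names inside the files would exchange the inputs of Chd7 replicate 2 and Chd8. Input 3 overlapped 52.9% (51.7 to 54.1) of the replicate 2 list and input 2 overlapped 18.1% (17.6 to 18.7) of the Chd8 list.

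How many Chd7 sites recurred was asked first. A minority of each Chd7 list was found in the other: 26.8% (25.6 to 28.0) of replicate 1 peaks overlapped a replicate 2 peak, and 22.3% (21.2 to 23.3) of replicate 2 peaks overlapped a replicate 1 peak. Randomly moved peaks overlapped in 0.167% and 0.139% of cases on average, with a one-sided permutation p = 0.001 each way, the smallest that 1000 placements can give. For replicate 1 peaks, placements drawn from input regions gave 1.56%, and those matched on gene ends, chosen after the data were seen, 1.21%. The overlaps defined 1383 reproducible Chd7 regions with a median width of 531 bp and a median fold, averaged over both libraries, of 4.13. Peaks with a higher fold recurred more often: with replicate 1 peaks split by fold into 4 equal groups, 20.5% (18.3 to 22.8) of the lowest and 32.4% (29.9 to 35.0) of the highest group were found in replicate 2. Within the reproducible regions the fold in replicate 1 was weakly related to that in replicate 2 across regions, which are not independent replicates (Spearman rho 0.12, Pearson r 0.25). The overlap was 4.50% with peaks of a −log10 q of at least 5, 0.743% with peaks of a fold of at least 5, 15.5% with peaks in the matching input removed and 10.4% with a reciprocal overlap of 50%, where random placements gave at most 0.103%. Fold scales differ between the libraries: 26.5% of listed replicate 1 peaks but 1.10% of replicate 2 peaks had a fold of at least 5. The 0.743% is therefore limited by the few replicate 2 peaks left.

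The next comparison asked how far both remodelers occupied the same sites. Nearly all reproducible Chd7 regions were also Chd8 sites: 1343 of 1383 (97.1%, 96.1 to 97.9) overlapped a Chd8 peak, against 0.809% for randomly moved regions (one-sided permutation p = 0.001, the smallest possible). Placements drawn from input regions gave 2.25%, and placements matched on gene ends, chosen after the data were seen, 8.06% (permutation p = 0.001 for each). The reverse share was small, since 1356 of 18350 Chd8 peaks (7.39%, 7.02 to 7.78) overlapped a reproducible Chd7 region. Away from gene ends the sharing was also high: 492 of 520 Chd7 regions (94.6%, 92.3 to 96.4) overlapped a Chd8 peak, beside 851 of 863 (98.6%, 97.6 to 99.3) that touched a gene end. Chd8 peaks shared with Chd7 had a median fold of 5.39 against 4.41 for the others, a difference of 0.979 over peaks (two-sided permutation p = 1e-05, the smallest possible), and their median width was 719 bp against 361 bp. Reproducible Chd7 regions with and without Chd8 had median folds of 4.13 and 4.01 (1343 and 40 regions, permutation p = 0.106). Across shared regions, which are not independent replicates, the Chd7 and Chd8 folds were weakly related (Spearman rho 0.14, Pearson r 0.09).

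Single Chd7 libraries shared fewer peaks with Chd8 than the reproducible regions did. Of Chd7 replicate 2, which shared a mock with Chd8, 62.2% (61.0 to 63.4) of the peaks overlapped a Chd8 peak, and of replicate 1, with a mock of its own, 78.8% (77.7 to 79.9) did. The 97.1% rests on regions found in both libraries and may rest partly on the long Chd8 list. With equal numbers of highest-fold peaks, where Chd7 replicate 2 was also shortened, it was 67.4%, against 0.279% for random placement. With a reciprocal overlap of 50% it was 64.95%, against 0.180%. With peaks of the matching input removed from each list it was 46.8%, against 0.421%. That setting takes Chd7 and Chd8 peaks away by different inputs. It was 0% of the 5 Chd7 regions left by a −log10 q of at least 5, where random placement gave 0.08%, and 40% of the 10 regions left by a fold of at least 5, against 0.25%.

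**Figure D1:**
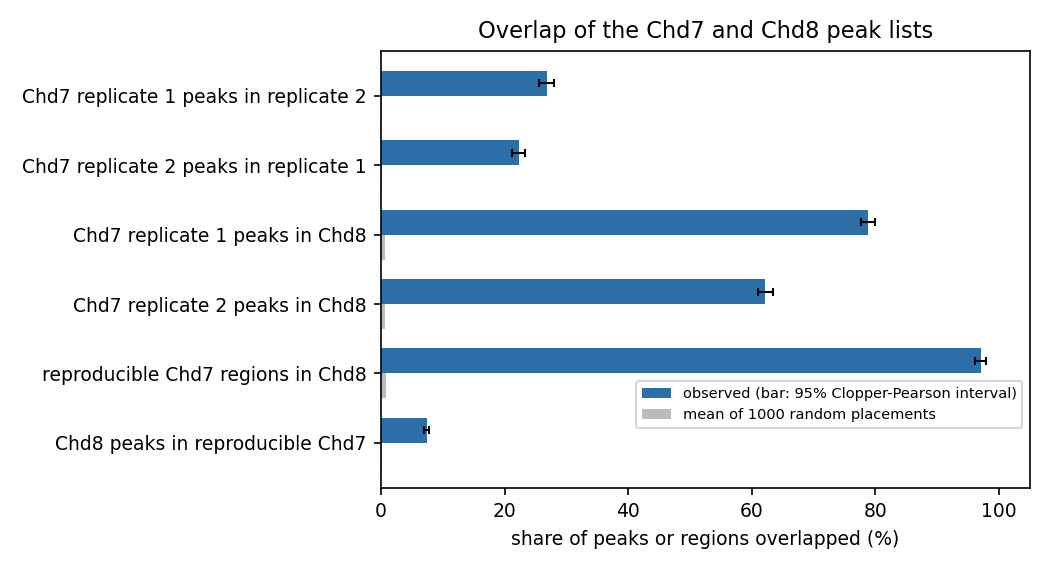
Share of peaks (%) in each list that overlapped a peak of another ChIP list by at least 1 bp, with 95% exact binomial intervals over peaks, beside the mean share for 1000 random placements. Reproducible Chd7 regions sit at 97.1% in Chd8, whereas Chd8 peaks sit at 7.39% in reproducible Chd7 regions.

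Both remodelers lay at gene ends far more often than their controls. The annotation gave no strand, so a gene end is either boundary of a protein-coding gene, within 1 kb. By midpoint, 60.6% (58.0 to 63.2) of reproducible Chd7 regions lay at a gene end, 25.2% inside a gene and 14.2% between genes. The Chd8 list had 44.9% (44.2 to 45.7) at gene ends, 34.1% inside genes and 21.0% between genes. Chd7 replicates 1 and 2 alone had 36.4% (35.1 to 37.7) and 50.2% (48.9 to 51.4) at gene ends. Mock peaks had 6.74% (2.51 to 14.1) and 4.08% (1.12 to 10.1) there, inputs 1, 2 and 3 had 3.95%, 3.30% and 10.9%, and randomly placed Chd8 peaks had 3.20%. With matching-input peaks removed the gene-end shares were 46.6% for Chd7 and 30.2% for Chd8. Chd8 peaks of higher fold lay there more often, 60.9% at a fold of at least 5 and 69.0% at a −log10 q of at least 5, while the few Chd7 regions left by these settings (10 and 5) had 20% and 0%.

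**Figure D2:**
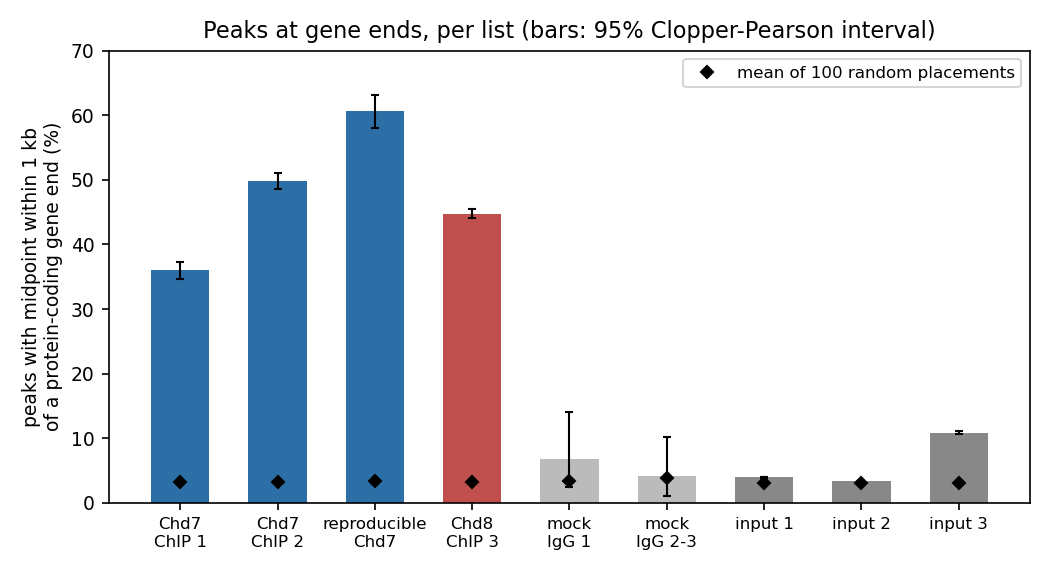
Share of peaks (%) whose midpoint lay within 1 kb of an end of a protein-coding gene, for each library and for the reproducible Chd7 regions, with 95% exact binomial intervals over peaks; markers give random placements. ChIP lists sit between 36.01% and 60.6%, inputs between 3.30% and 10.9%.

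Genes with Chd7 at an end were almost always genes with Chd8 at an end. Of 21887 protein-coding genes, 1057 (4.83%) had a reproducible Chd7 region at an end and 8966 (40.97%) a Chd8 peak. Both were found at 1045 genes, 98.9% of the Chd7 genes, against 38.0% of the genes without Chd7 (odds ratio 142, 95% interval 80.3 to 251, two-sided Fisher's exact test with a p below the range of the computation). Chd7 replicate 2 alone, which shared a mock with the Chd8 library, gave 90.3% (odds ratio 20.7, 18.5 to 23.2), and replicate 1 alone gave 96.0% (odds ratio 45.04, 36.5 to 55.6). Neighbouring genes can share a peak, so genes are not independent. With matching-input peaks removed the share was 33.1%, against 16.4% of the genes without Chd7 in that setting (ratio 2.01, exact p = 2.80e-15).

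The highest mean fold of a reproducible Chd7 region at a gene end, 5.61 (7.04 and 4.18 in replicates 1 and 2), was at chromosome 5, 120612861 to 120613438, between Ddx54, an RNA helicase gene, and Rita1. Next came the region shared by Cfap70 and Mrps16, a mitochondrial ribosomal protein gene, with 5.43, Oga, the enzyme that removes O-GlcNAc from proteins, with 5.30, and Birc6, an inhibitor of apoptosis with ubiquitin ligase activity, with 5.24. Mlec (5.18), the pair Kif22 and Maz (5.18) and Pgp (5.16) completed the 10 genes.

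The highest Chd8 peak at a gene end, with a fold of 23.6, covered an end of Kmt5b, a histone lysine methyltransferase, on chromosome 19 from 3767269 to 3769153. Every input also had a peak at an end of Kmt5b, without a check that it was the same end, and neither Chd7 library had one. Ccdc124 had 20.1, the kinetochore gene Nuf2 had 15.6, Fbxo36 had 14.8, Septin7, a cytoskeletal GTPase, had 14.3, Gnb2, a G protein beta subunit, had 14.0, Zc3h6 had 14.0 and Sfswap, a splicing regulator, had 13.1. Ranked by the geometric mean of Chd7 and Chd8 fold, the strongest shared sites were at Gnb2 (8.15), Zc3h6 (7.64), Septin7 (7.33), Mtf2 (7.27), a Polycomb-associated gene, Cltc (7.15), which encodes clathrin heavy chain, the calmodulin gene Calm3 (7.12), the Mediator subunit gene Med25 (7.11), the pair Eef1b2 and Ndufs1 (6.83), and Zfp143 (6.81), a zinc finger transcription factor. Among listed genes, shared sites stood at Rbm25 (6.55), Nfia (6.42), Kmt2d (6.37), Rps14 (6.10), Chd2 (6.06), Rpl37 (6.03), Cyp51 (5.85), Gas1 (5.31), Idi1 (5.09) and, at the ends of Pmel and Rab5b, beside Cdk2 (4.75).

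Gene lists fixed beforehand were then tested at Chd7 gene ends. RNA splicing, cholesterol synthesis, OPC identity and autism risk genes had reproducible Chd7 regions more often than other genes, of which 4.8% did. Splicing genes had 10 of 41 (24.4%, 12.4 to 40.3, odds ratio 6.41, adjusted exact p = 2.83e-04). Among them were Rbm25 (mean fold 4.70), Sf3b2 (4.15) and Srsf1 (3.74). At Srsf1 the merged region reached the gene-end window, but its replicate 2 peak did not. Cholesterol synthesis had 6 of 24 (25%, 9.77 to 46.7, odds ratio 6.60, adjusted exact p = 0.00596), with Idi1 (4.73), Hmgcs1 (4.08) and Cyp51 (3.84). OPC identity had 5 of 28 (17.9%, 6.06 to 36.9, odds ratio 4.30, adjusted exact p = 0.0380), namely Gpr17, a receptor of committed precursors, Bcan, a proteoglycan core protein, Matn4, the Notch effector Hes5 and Sox11. Autism risk genes had 9 of 66 (13.6%, 6.43 to 24.3, odds ratio 3.13, adjusted exact p = 0.0215), including Tcf4, Dyrk1a and Setd5. Chromatin regulators had 7 of 56 (adjusted exact p = 0.0531), among them Smarca4, Arid1a and Ezh2, and Notch, Wnt and Hedgehog pathway genes 5 of 44 (adjusted exact p = 0.149): Hes1, Hes5, Hes6, Fzd1 and Gas1.

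Other groups did not pass that test. Ribosomal protein genes had 5 of 78 (Rpl27, Rpl37, Rps14, Rps19 and Rps27a), cell cycle genes 2 of 38 (Ccna2 and Cdt1), oligodendrocyte differentiation and myelin genes 1 of 35 (Sirt2, a deacetylase) and p53 pathway and apoptosis genes 1 of 33 (Bcl2l11, a pro-apoptotic gene), with adjusted exact p of 0.714, 0.815, 1 and 1. No member was found among 22 astrocyte, 33 neuron, 25 microglia, 30 endothelial and mural or 25 hepatocyte genes (adjusted exact p from 0.714 to 0.790), which allows shares of up to 15.4%, 10.6%, 13.7%, 11.6% and 13.7% by the exact interval. Members named here and in the preceding paragraph that the naming rule does not cover were chosen after their values were seen. Tests were two-sided Fisher's exact tests adjusted over 15 lists. The splicing call held in 9 of 12 alternatives (adjusted exact p from 7.83e-06 to 1), OPC identity in 8 (0.00111 to 1), autism risk in 7 (0.00532 to 1) and cholesterol synthesis in 6 (0.00191 to 1). All 4 ended with a reciprocal overlap of 50% or a fold of at least 5, cholesterol synthesis and autism risk also with matching-input peaks removed, and OPC identity with equal numbers of highest-fold peaks (14.3%). A background of genes with an end in 2 or more inputs left only splicing called (34.8%), and any-input removal, chosen after the data were seen, only OPC identity (10.7%, beside 0% for splicing and cholesterol synthesis). Input 1 itself passed the test for splicing, 17 of 41, and cholesterol synthesis, 11 of 24 (adjusted exact p = 0.0215 and 0.0313), but not for OPC identity or autism risk (1 and 0.679). Input 2 passed for none of the 4. Input 3, which the track names would assign to Chd7 replicate 2, passed for splicing, 36 of 41, and autism risk, 42 of 66 (adjusted exact p = 4.03e-07 and 0.00849). It did not pass for OPC identity or cholesterol synthesis (adjusted exact p = 0.213 and 0.191). Replicate 2 alone gave 10 called lists, without cholesterol synthesis: 7 above other genes and 3 below, namely microglia, endothelial and mural, and hepatocyte genes. Replicate 1 alone gave 6, all above.

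At Chd8 gene ends 8 lists were occupied more often than other genes and 3 less often. Chd8 lay at 40 of 41 splicing genes (97.6%, 87.1 to 99.9, adjusted exact p = 5.51e-14), 74 of 78 ribosomal protein genes (94.9%, 87.4 to 98.6, adjusted exact p = 4.76e-23) and 24 of 28 OPC identity genes (85.7%, 67.3 to 96.0, odds ratio 8.67, adjusted exact p = 5.27e-06), against 41% of other genes. Chromatin regulators had 43 of 56 (76.8%, adjusted exact p = 3.30e-07), cholesterol synthesis 18 of 24 (75%, adjusted exact p = 0.00206), cell cycle 27 of 38 (71.1%, adjusted exact p = 4.45e-04), autism risk 46 of 66 (69.7%, adjusted exact p = 8.75e-06) and Notch, Wnt and Hedgehog pathways 26 of 44 (59.1%, adjusted exact p = 0.0277). Examples with their strongest peak at their own end were Snrnp70 (fold 10.5), Rps12 (9.39), Cyp51 (8.90), Rbl1 (8.85) and Ctnnb1 (8.08). Occupancy was lower than in other genes for endothelial and mural markers, 0 of 30 (adjusted exact p = 6.16e-07), hepatocyte genes, 2 of 25 (8.00%, adjusted exact p = 7.24e-04), and microglia markers, 4 of 25 (16.0%, adjusted exact p = 0.0196).

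Oligodendrocyte differentiation and myelin genes had Chd8 at 16 of 35 ends (45.7%, 28.8 to 63.4, adjusted exact p = 0.651), p53 pathway and apoptosis genes at 19 of 33 (57.6%, adjusted exact p = 0.0863), astrocyte markers at 10 of 22 (45.5%, adjusted exact p = 0.671) and neuron markers at 8 of 33 (24.2%, adjusted exact p = 0.0659). Input 3 had peaks at 36 of 41 splicing, 58 of 78 ribosomal protein and 42 of 56 chromatin regulator genes, which passed the same test (adjusted exact p = 4.03e-07, 1.87e-06 and 4.74e-05). So did 31 of 44 Notch, Wnt and Hedgehog pathway, 42 of 66 autism risk, 26 of 38 cell cycle and 23 of 33 p53 pathway and apoptosis genes (adjusted exact p = 0.00441, 0.00849, 0.0107 and 0.0107). Input 3 did not pass for OPC identity, 17 of 28, or cholesterol synthesis, 15 of 24 (adjusted exact p = 0.213 and 0.191). With peaks in that input removed, Chd8 lay at 60.7% of OPC identity genes (other genes 16.7%) and 32.1% of ribosomal protein genes, both still called, at 34.3% of oligodendrocyte differentiation genes, then called, and at 22.0% of splicing and 26.8% of chromatin regulator genes, no longer called. Alternatives that called the lists numbered 10 of 10 for ribosomal proteins, 9 for autism risk, 8 each for splicing and endothelial and mural markers, 7 for chromatin regulators, 6 each for OPC identity and cell cycle, and 4 each for cholesterol synthesis, Notch, Wnt and Hedgehog pathways, microglia and hepatocyte genes. The OPC identity call ended under the settings that kept only stronger peaks (14.3% to 25%) and among genes seen in 2 or more inputs (100%).

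**Figure D3:**
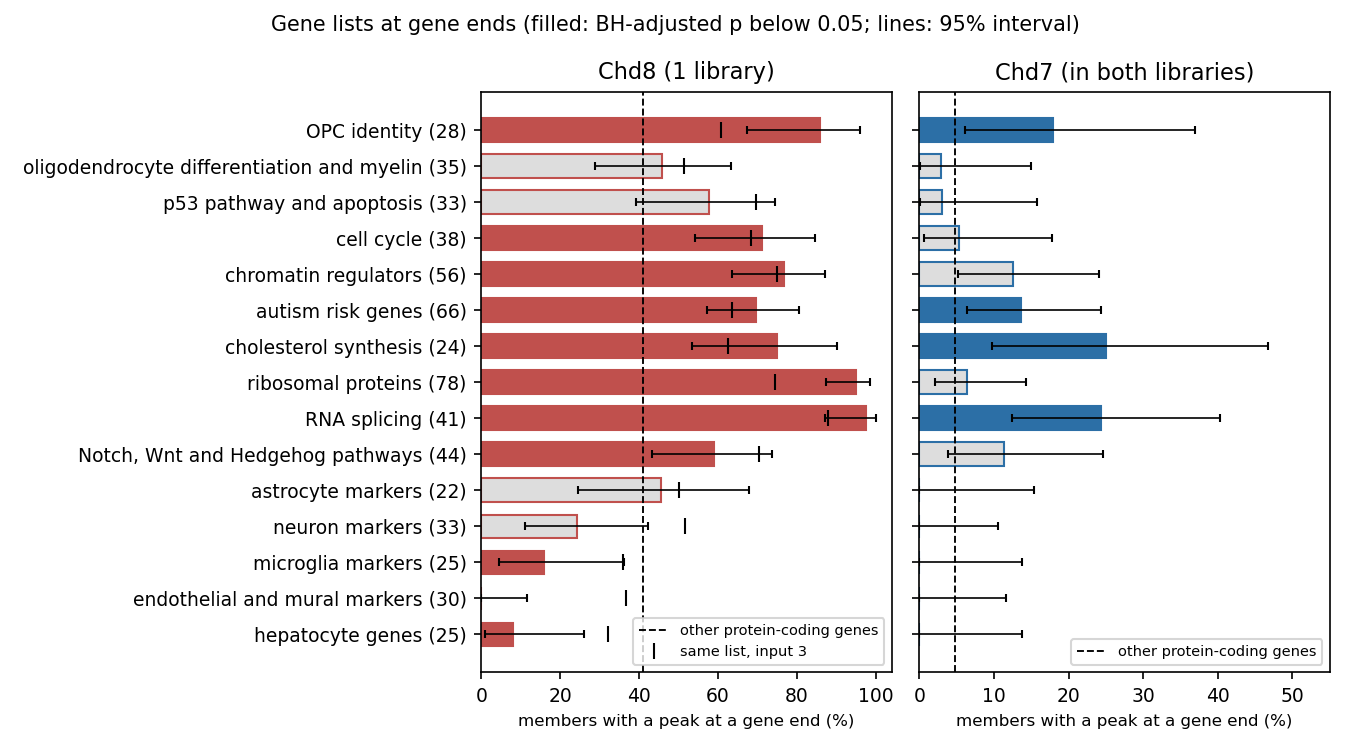
Members of each list (number in brackets) with a Chd8 peak (left) or reproducible Chd7 region (right) within 1 kb of a gene end (%), with 95% exact binomial intervals over genes; filled bars passed the adjusted test, dashed lines mark other protein-coding genes and short vertical marks the same list in input 3. OPC identity genes reach 85.7% with Chd8 and 17.9% with Chd7, endothelial and mural markers 0% with both.

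Whole loci, the gene body with 10 kb on both sides, were examined next, since remodelers also lie at distal sites. At the loci of OPC identity genes, Chd8 peaks were found in 27 of 28 (96.4%, against 61.6% of random lists matched on locus length, adjusted permutation p = 0.001) and reproducible Chd7 regions in 9 of 28 (32.1% against 9.06%, adjusted permutation p = 0.012). The Chd7 members were Olig2, Cspg4, Gpr17, Bcan, Matn4, Hes5, Traf4, Xylt1 and Sox11. Beside Olig2, a lineage-determining transcription factor of oligodendrocytes, a reproducible Chd7 region with a mean fold of 4.63 (5.71 and 3.56) spanned 91233368 to 91233986 on chromosome 16, 4691 bp beyond the gene's higher-coordinate boundary, within a Chd8 peak of fold 6.88, and part of it also lay under an input 3 peak. At Gpr17 the Chd7 region of mean fold 4.21 (4.95 and 3.48) at chromosome 18, 31949637 to 31950423, covered the gene's end, was shared with Chd8 (5.94) and had no input peak.

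Further reproducible Chd7 regions lay inside Xylt1 (5.31), Traf4 (4.23) and Cspg4 (4.12), which encodes the NG2 proteoglycan, at the end of Bcan (4.22), and beside Hes5, where the stronger region (4.56) was at the end of the neighbouring Pank4 and the one at Hes5 itself had 4.46. Among oligodendrocyte differentiation genes they lay at Sirt2 (4.93, an end shared with Nfkbib), inside Zeb2 (4.40) and beside Cldn11 (4.25). High Chd8 folds in both lists were inside Tnr (7.85), Fa2h (7.56), Ugt8a (7.41), Xylt1 (7.24), Cacng4 (7.05) and Epn2 (6.86), beside Olig2 (6.88), Traf4 (6.48) and Gpr17 (6.47), and at the end of Hes5 (6.47). Fa2h and Ugt8a are enzymes of myelin lipid synthesis, whose loci held no reproducible Chd7 region. At Ugt8a each Chd7 library had a peak at a gene end (4.51 and 3.87 in replicates 1 and 2), but these did not coincide. The Fa2h locus had no peak in either Chd7 library.

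Several regulators of the lineage had Chd8 without a reproducible Chd7 region. The loci of Olig1, Sox10, Pdgfra, Nkx2-2, Myrf, Mbp, Trp53, Cdkn1a, Chd7 and Chd8 held Chd8 peaks, with strongest folds of 5.33, 4.79, 5.55, 5.34, 4.32, 4.95, 5.46, 4.63, 5.28 and 6.92 in that order. The Myrf peak lay at the ends of Tmem258 and Fen1, the Sox10 peak at an end of Polr2f, and the Trp53 peak at an end it shares with Wrap53. At 6 of these loci, Olig1, Sox10, Pdgfra, Nkx2-2, Mbp and Chd7, both Chd7 libraries had peaks, but at places that did not coincide.

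**Figure D4:**
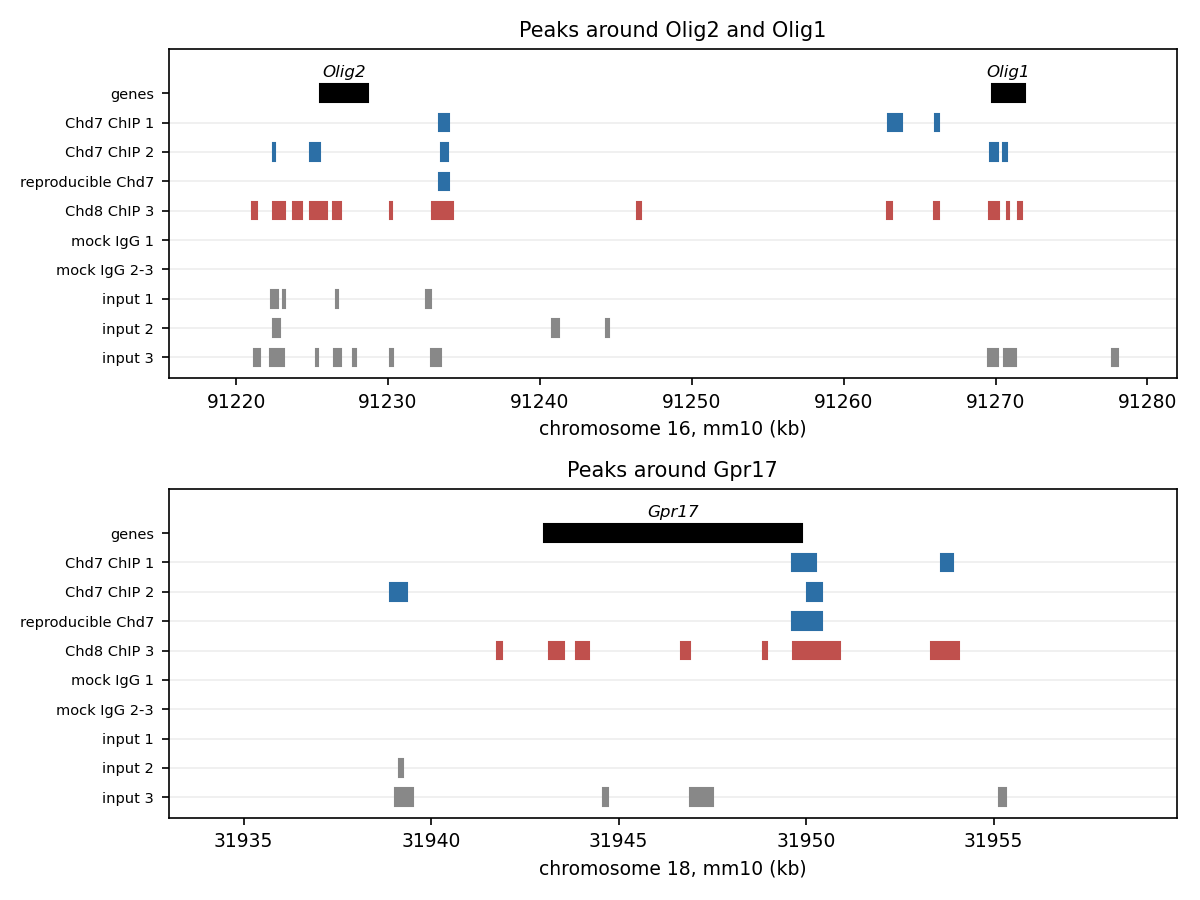
Peaks of each library around Olig2 and Olig1 on chromosome 16 and around Gpr17 on chromosome 18 (mm10 position in kb), with the genes on top and the reproducible Chd7 regions on their own line. Beside Olig2 both Chd7 libraries and Chd8 have a peak at 91233368 to 91233986, with an input 3 peak over part of it, whereas at Olig1 the Chd7 peaks of both libraries lie apart.

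Beyond the OPC list, Chd7 loci passed the test for splicing genes, 12 of 41 (29.3% against 8.78%, adjusted permutation p = 0.012), and for no other list. Their adjusted p were 0.0820 for autism risk (14 of 66, with Gigyf1 through a region at the end of Gnb2), 0.0900 for chromatin regulators (12 of 56, with Arid1a at 4.83), 0.123 for cholesterol synthesis (6 of 24), and from 0.244 to 1 for the rest, among them Notch1 (4.54), Nfia, an astrocyte-list gene (5.58), Ccnd1 (4.67) and Rps2 (4.61). Some members were counted through a neighbour: Hdac3 through Diaph1, Casp9 through Dnajc16, Aurkb through Borcs6, Cd68 through Eif4a1 and Slc17a7 through Aldh16a1. Both Chd7 locus calls were lost with a reciprocal overlap of 50%, a fold or −log10 q of at least 5, or regions away from gene ends alone, a setting chosen after the data were seen. Chd7 replicates 1 and 2 alone gave 7 and 8 called lists, of which 1 each, endothelial and mural markers, was below matched lists.

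Chd8 loci passed the test for 9 lists. Higher than in matched lists were ribosomal proteins with 78 of 78, OPC identity, splicing with 40 of 41, chromatin regulators with 53 of 56, autism risk with 60 of 66, cell cycle with 33 of 38 and Notch, Wnt and Hedgehog pathways with 36 of 44 (adjusted permutation p from 7.50e-04 to 0.0217). Lower were endothelial and mural markers with 4 of 30 (13.3% against 61.6%, adjusted permutation p = 7.50e-04) and hepatocyte genes with 7 of 25 (28.0% against 59.0%, adjusted permutation p = 0.00675). Of 7 alternatives, 7 kept the call for OPC identity, chromatin regulators and autism risk, 6 for ribosomal proteins and for endothelial and mural markers, and 5 for splicing and cell cycle. Notch, Wnt and Hedgehog pathways kept it in 3 (adjusted permutation p from 0.002 to 0.978) and hepatocyte genes in 2 (0.00788 to 0.799). The strongest peaks of list members were often at their own or a close neighbour's end. That of Snap25 (5.26) was at its own end. Shared ends were those of Mcm7 (12.9) with Ap4m1, Rps18 (9.37) with Vps52, Pidd1 (6.93) with Rplp2, and Apoa2 with Tomm40l. Other members had their strongest peak at a neighbour's end: Trip12 through Fbxo36, Srsf10 through Pnrc2, Apc through Srp19, and Tm7sf2 through Fau and Mrpl49. So did Casp9 through Dnajc16, Hp through Txnl4b and Dhx38, Aif1 through Prrc2a, Cd68 through Mpdu1, and Slc32a1 through Actr5. Peaks in Kmt2d (10.9), Nfia (8.30) and Vwf (6.87) were inside the gene, and that at Ramp2 (6.81) lay beside it.

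Away from gene ends, a setting chosen after the data were seen, Chd8 peaks lay in 92.9% of OPC identity loci against 27.0% of matched lists and in 57.1% of oligodendrocyte differentiation and myelin loci against 30.0% (adjusted permutation p = 0.002 for both). With all Chd8 peaks the latter list had 24 of 35 loci (68.6% against 65.1%, adjusted permutation p = 0.864), and its adjusted p ranged from 0.002 to 0.866 over 7 alternatives. Ribosomal protein loci had 17.9% against 10.8% away from gene ends and splicing loci 19.5%, neither called.

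Whether list members had Chd7 more often than other genes was tested among the 12465 genes with either remodeler at the locus, without length matching. Of these genes 12444 had Chd8, and 1828 of the 1849 with a reproducible Chd7 region also had Chd8. The test therefore asks which loci with Chd8 also had Chd7, and it cannot show a preference for Chd7 over Chd8. No list passed (0 of 15 by Fisher's exact test, 2 at an unadjusted p under 0.05). OPC identity genes had Chd7 in 9 of 27 (33.3%, 16.5 to 54.0) against 14.8% of the other genes, and splicing genes in 12 of 40 (30.0%, 16.6 to 46.5), each with an adjusted exact p = 0.0959. Each Chd7 library alone gave 1 called list, OPC identity in replicate 1 (85.7%, adjusted exact p = 2.30e-06) and autism risk in replicate 2 (67.7%, adjusted exact p = 0.0489), so this count depended on how Chd7 sites were defined.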

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

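Tests with regions away from gene ends, the nearest gene end alone, peaks in any input removed, peaks far from mocks and placements matched on gene ends were chosen only after the results were seen. No paired analysis was possible because no result is a test across libraries. Of 87 alternatives for the summary results, 59 kept their direction and side of the threshold or stayed within their interval or 1.5 times the count, 15 called fewer lists, 5 called more, 7 left the interval and 1 turned direction; of 440 for single lists called in some setting, 300 did, 77 lost a call, 33 gained one and 30 turned direction. The overlap of Chd7 replicates kept its side in each alternative run, from 0.743% to 27.5%, as did co-occupancy, from 33.1% to 100%. Depth could not be varied, since the lists hold no reads, and Chd8 could not be checked by leaving out a library.

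With a −log10 q of at least 5, 5 Chd7 regions were left: 0% overlapped Chd8, 0% lay at gene ends and 0 lists were called at Chd7 loci; Chd8 had 69.0% at gene ends and 4 called lists at them, and co-occupancy and lists at Chd7 gene ends gave no value, as no gene was left. With a fold of at least 5 (10 Chd7 regions), gene-end shares were 20% for Chd7 and 60.9% for Chd8, and 0, 7 and 0 lists were called at Chd7 gene ends, Chd8 gene ends and Chd7 loci. Equal numbers of highest-fold peaks gave 60.8% and 7 lists for Chd8. In these settings fewer peaks were tested. Matching-input removal gave gene-end shares of 46.6% (Chd7) and 30.2% (Chd8) with 2 and 6 lists. A reciprocal overlap of 50% left 0 lists at Chd7 gene ends and 0 at loci, over 738 genes in place of 1849. A background of genes with an end in 2 or more inputs gave 1 list for Chd7 and 4 for Chd8, with fewer genes tested. Removal of peaks in any input gave 1 and 4, and regions away from gene ends 0 lists at Chd7 loci. Single Chd7 libraries, with more peaks, gave 6 to 10 lists at gene ends (up to 3 of them lower than other genes), 7 to 8 at loci (1 lower in each) and 1 to 1 against Chd8. Where no construction is named, the cause was not tested.

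Among lists called in some setting, these turned direction, in percent of members; none but p53 was past the threshold there. Lists called in no setting also turned, such as oligodendrocyte differentiation and astrocyte markers at Chd7 loci. Oligodendrocyte differentiation at Chd8 gene ends fell below other genes with a −log10 q of at least 5 (2.86%), a fold of at least 5 (5.71%), equal numbers (5.71%) and the input background (60%), and at Chd8 loci with the former settings (8.57%, 22.9% and 22.9%). The p53 list at Chd8 gene ends did so at 3.03%, 9.09% and 9.09%, with matching-input peaks removed (12.1%) and with any-input peaks removed (9.09%). At Chd7 gene ends it turned higher with matching-input peaks removed (3.03%) and in single libraries (12.1% to 33.3%), and at Chd7 loci with equal numbers (9.09%), without sex chromosomes (9.68%), away from gene ends (3.03%) and in single libraries (30.3% to 51.5%); it passed the threshold in replicate 2 alone (adjusted p = 0.0316 at gene ends by an exact and 0.0315 at loci by a permutation test, from there to 1 over the alternatives). Cholesterol synthesis at Chd8 gene ends turned at 16.7% (matching input) and 8.33% (any input) and at Chd8 loci at 25% (matching input); neuron markers at Chd8 gene ends turned at 18.2% and 15.2%. Ribosomal proteins at Chd7 gene ends turned with the input background (6.38%) and the nearest end (3.85%), cell cycle (71.4%) and Notch, Wnt and Hedgehog pathways (68.8%) at Chd8 gene ends with the input background, and autism risk at Chd7 loci away from gene ends (3.03%). The cause was not tested.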

Other observations

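The test of tRNA genes and the tests of the 3 patterns below were all chosen after the main results were seen; their predictions were written before each test was run, except for the test of the highest-fold group with the shortened Chd8 list, which followed the shares by fold group.

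Chd8 also lay at genes outside the protein-coding set. Of 408 tRNA genes, transcribed by RNA polymerase III, 147 (36.03%, 31.4 to 40.9) had a Chd8 peak within 500 bp, against 5.30% of the same windows moved by 20 kb either way (odds ratio 10.1, two-sided Fisher's exact test p = 4.32e-42). Among tRNA genes away from ends of protein-coding genes the shares were 29.9% of 348 and 3.86% (odds ratio 10.6, exact p = 7.65e-32). Over all 408 tRNA genes, with Chd8 peaks under input 3 left out, the shares were 21.8% and 2.83%. Input 3 itself had 16.4% and 8.62% (exact p = 7.39e-05). Single Chd7 libraries were also raised at tRNA genes. Replicate 1 had peaks at 7.84% of them and 0.862% of moved windows (odds ratio 9.79, exact p = 3.05e-10). Replicate 2 had 6.86% and 1.48% (odds ratio 4.91, exact p = 3.05e-06). The signal at tRNA genes was therefore not particular to the Chd8 library. Reproducible Chd7 regions had 0.490%, beside 0.493%, so the Chd7 peaks there rarely coincided. That Chd8 occupies tRNA genes is a hypothesis from 1 library; tRNA genes are repeated and clustered, and reads shared between copies were not tested.

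Other noncoding classes away from protein-coding ends had Chd8 within 1 kb of a gene end less often than tRNA genes did in that window (32.6% of 341, 27.6 to 37.8), which is wider than the 500 bp used above and leaves out more genes. The shares were 7.15% (6.66 to 7.68) of lncRNA, 4.26% (3.08 to 5.71) of miRNA, 2.78% (1.82 to 4.05) of snRNA, 1.11% (0.592 to 1.89) of snoRNA genes and 0.692% (0.535 to 0.882) of pseudogenes. Transcribed pseudogenes, a class of their own in the annotation, had 4.38% of 411 (2.62 to 6.83) with Chd8 and 10.5% with input 3. Input 3 had 16.1%, 14.6%, 13.3%, 8.88%, 10.5% and 7.31% in the order tRNA, lncRNA, miRNA, snRNA, snoRNA and pseudogene, but that list is longer, so its shares were not set against those of Chd8.

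Chd7 replicate 1 shared more of its peaks with Chd8 (78.8%) than with Chd7 replicate 2 (26.8%), although Chd8 was drawn with the other antibody and replicate 1 shared its mock with neither. The Chd8 list shortened to its highest-fold peaks, as many as replicate 2 holds, still overlapped 47.3% (46.0 to 48.7). This was the outcome set against list length as the cause. The cut kept the strongest Chd8 peaks and set them against the whole replicate 2 list, so it cannot exclude list length. Filtering also differed and was not tested: 62756 peak numbers were missing from the replicate 2 list, 1037 from replicate 1 and 3021 from Chd8. Regions seen in input did not account for the difference from the shortened list. Outside all inputs the shares were 36.5% (34.9 to 38.2) for the shortened Chd8 list and 12.3% (11.2 to 13.5) for replicate 2. Weak peaks of replicate 1 did not account for the whole difference either: in its highest fold group 59.2% (56.5 to 61.9) were under the shortened Chd8 list and 88.4% (86.5 to 90.04) under the full list, against 32.4% (29.9 to 35.0) in replicate 2. In the lowest fold group the shares were 36.7%, 68.5% and 20.5%. Peaks near the calling threshold stay open as a candidate explanation of part of the low replicate overlap, since 32.4% of the highest and 20.5% of the lowest group recurred, and sites of replicate 2 that stayed under its own threshold were not tested. No biological explanation was tested, and antibody cross-reaction between the remodelers was not tested either.

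Input 3 lay at gene ends (10.9%, 10.7 to 11.1) more often than inputs 1 and 2 (3.95% and 3.30%). Shortened to the length of input 3 by their highest-fold peaks, inputs 1 and 2 had at most 3.74% (3.62 to 3.87). That cut alone cannot exclude list length, since it kept only the strongest peaks. By number, however, input 3 held 9969 gene-end peaks, against 4325 and 5896 in the longer lists of inputs 1 and 2. No choice of peaks from those lists at that length could reach its share, so the length of the listed peaks did not account for it. Filtering differed too and was not tested: 173227 peak numbers were missing from the input 3 list, 25987 from input 1 and 46513 from input 2. Chd8 ChIP material in input 3 cannot be told apart from open chromatin that both libraries read: 49.4% (48.4 to 50.4) of its gene-end peaks were under a Chd8 peak, below the 90% set for that cause, with an interval that spans the bound of 50% set against it. Away from gene ends 3.03% were. No biological explanation was tested.

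Fewer X-linked than autosomal genes had a Chd8 peak at an end, 18.8% (16.4 to 21.5) against 42.5% (41.8 to 43.2). Multicopy families did not account for it, since without predicted genes and neighbouring families the odds ratio was 0.327 (0.274 to 0.390, Fisher's exact p = 1.43e-39), beside 0.314 with all genes. A weaker signal on X stays open: X-linked Chd8 peaks at gene ends had a median fold of 4.47 against 4.71 (permutation p = 0.00685). Fold is a ratio to a local background, so this difference does not measure the number of X copies. The sex of the mice is not given in the sources used here. The inputs showed the same direction with odds ratios below that of Chd8, 0.0596, 0.156 and 0.0903, as did Chd7 replicates 1 and 2 with 0.0336 and 0.184. No biological explanation was tested.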
